A study of Homo sapiens with 6 samples.

How the data were processed

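HES3, a line of human embryonic stem cells, had been grown on human fibroblast feeder cells and was then freed of most feeders with a cell strainer, a step that per the labels typically removed 90% of them. The cells were plated on fibronectin for 2 days and treated for 3 days with Activin A, a ligand that signals through the Nodal receptors, or with Activin A and bone morphogenetic protein 4 (BMP4), each at 50 ng/ml per the labels. Total RNA was labelled with biotin and hybridised to Illumina bead arrays, 3 arrays for each treatment. The labels' treatment text names both factors for every sample, so the split into treatments rests on the sample titles and source names. The series' design text calls the replicates biological.

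The deposited probe signals are intensity values on a linear scale, not normalized between arrays per the file headers, and the values show that background had already been subtracted, since 22.2% to 24.6% of an array's signals were negative. The deposited detection column is a score that the file headers name a detection p-value. The score rose with the signal (Spearman correlation across probes at least 0.98 on each array), so it was read as 1 minus that p-value. The authors' processed values are on a log2 scale. Over 6507 probes with a signal above 100 on all arrays they equalled the log2 signal plus a probe constant and an array constant to within 1.20e-06. The array constants followed the 75th percentile of the array to within 0.00166, and the array medians lay between -0.147 and 0.147. Direction and scale were thus settled from the values, and the baseline on which each probe was centred stays unknown. The scanner software is not given in the sources used here.

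Signals were background-corrected and quantile-normalized with neqc in limma 3.58.1 under R 4.3.3, with an offset of 16 and negative controls inferred from the detection p-values. A probe was tested if its detection p was under 0.01 on at least 3 of the 6 arrays, which kept 10116 of 24526 probes. The platform annotation gave 1 gene symbol for 21834 probes and none for 2692, and 0 probes had several. The gene ID of 21813 probes was found in a RefSeq gene table and gave the current symbol, and the file's symbol was kept for the others. No coordinates are printed, because the table's assembly is not tied to the array. A gene with several tested probes was represented by the probe with the highest mean, which gave 8186 genes. Of 924 genes with more than 1 tested probe, 4 had probes past the threshold in both directions.

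Treatments were compared with lmFit and eBayes in limma, with treatment as the only term, a two-sided test and Benjamini-Hochberg adjustment over all tested probes at a threshold of 0.05. A stricter count also asked for a log2 difference of at least 1. Differences are Activin A + BMP4 minus Activin A. A total of 22 gene lists were fixed before the data were examined and tested with camera, at a preset inter-gene correlation of 0.01 and with adjustment over the lists. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, were run beside it. Array-level values were compared with exact two-sided permutation tests, for which 3 arrays against 3 give no p below 0.1. A probe with no array of a treatment above background has only a bound there. Its fold is given as "at least", from the bright treatment's mean against, per array, the higher of the lowest normalized value among detected probes and the probe's own. Such a bound holds for its background correction alone, so after the data had been seen it was also computed with normexp and an offset of 50.

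The genes named were chosen by a rule fixed before the data were examined. They are the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays did not overlap between treatments, up to 3 members of each list past the threshold with the largest differences, and 15 fixed genes of endoderm, primitive streak, pluripotency and BMP signalling. Other genes named are list members outside this rule, chosen after their values were seen. Further lists of fibroblast, leukocyte and inflammatory cytokine genes were written after the first results, and their use is described with the other observations.

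The limma fit and camera were tested on simulated normalized values with 200 of 10116 probes changed, in 10 runs. Background correction, normalization, the filter and the choice of probe per gene were not part of this test. For Activin A + BMP4 against Activin A, 32.1% of simulated log2 differences of 0.5 were recovered, 98.1% of those of 1 and 100% of those of 2, and 5.00% of the calls were false. A simulated list of 20 genes moved by 0.5 was found in 10 of 10 runs, and 0 of 210 unmoved lists were called. The simulated genes varied independently, so this does not test the preset correlation. In the real data 35.4% of probes passed the threshold, a far larger share than was simulated, so the recovery there may differ.

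The alternatives tried were 2 other background corrections, 2 other normalizations, the authors' values, 2 other filters, 2 other variance models, the chip as a random block, the replicate number as a block, leaving out each array, and the mean of a gene's probes. With no background correction, signals under 1 were set to 1 before log2 was taken. The number of arrays limits the precision. The Activin A arrays shared 1 chip, and the Activin A + BMP4 arrays lay on 2 others, so each chip held a single treatment.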

Results

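The arrays measured transcripts in HES3 cells after 3 days of Activin A or of Activin A + BMP4, with 3 arrays in each treatment. Probes detected per array numbered 9348 to 10460. Detected probes made up 40.4% ± 0.472 (SD, n = 3) of the array with Activin A and 40.1% ± 2.33 (SD, n = 3) with both factors (exact permutation test, two-sided, p = 0.9). Correlations of normalized log2 values across tested probes were at least 0.985 within treatments and 0.926 to 0.945 between them. The first principal component held 78.2% of the variance.

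The comparison asked how adding BMP4 to Activin A altered transcript levels during endoderm induction. With BMP4, most tested genes of the definitive endoderm, primitive streak and BMP target lists were higher, 10 of 20 pluripotency genes were lower, and 17 of 22 fibroblast feeder markers were lower while 4 were higher. With an estimated correlation none of these list calls held (camera adjusted p = 0.0921, and 0.101 for the feeder markers). SOX17, a transcription factor of definitive endoderm, was 7.23-fold higher (log2 difference 2.85 ± 0.11 SE), and SOX2, a pluripotency and neural factor, was 9.65-fold lower (log2 difference -3.27 ± 0.13 SE). Of 8186 genes tested, 1444 were higher and 1483 lower with BMP4 by limma at the adjusted threshold, and 328 and 442 of these differed at least 2-fold. Higher genes made up 49.3% of the changed genes. Quantile normalization gives all arrays a common distribution, so an even share does not show that rises and falls balanced in the cells. Arrays of the treatments did not overlap for 50.2% of genes, against 10% by chance. The median of the fibroblast feeder markers differed by -1.33 on the same arrays. Each chip held 1 treatment, so the difference between treatments includes any difference between their chips. Under the normexp correction the 2-fold counts were 191 and 248, and among probes detected on all 6 arrays they were 210 and 279.

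The genes with the largest rises included GRP, which encodes gastrin-releasing peptide, and APLNR, the apelin receptor. Neither was above background on any Activin A array, and they were at least 21.9-fold and at least 14.9-fold higher, or at least 11.5-fold and 7.95-fold under the normexp correction. The value of GRP is that of its brighter probe, and its other probe was at least 5.11-fold higher (3.06-fold under normexp). PEG10 and MIR9-1HG, also not above background with Activin A, were at least 7.99-fold and at least 6.98-fold higher (4.50-fold and 3.99-fold under normexp). MFAP4, a microfibril-associated protein, was 10.4-fold higher, and the neuropeptide gene NMU was 10.1-fold higher. TMOD1 and PRSS35 rose 8.32-fold and 8.20-fold. The rule that chose these 8 genes required arrays without overlap and an adjusted p under 0.05. Their limma adjusted p was 2.10e-05 for TMOD1 and lower for the other 7.

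Among the largest falls, TXNIP, which encodes thioredoxin-interacting protein, was not above background on any Activin A + BMP4 array and was at least 5.27-fold lower, or 3.16-fold under normexp. CAMKV, IGSF21 and LCE2A were likewise not above background there, at least 6.08-fold, at least 3.92-fold and at least 3.88-fold lower, and with normexp these bounds were 3.56-fold, 2.48-fold and 2.45-fold. LOXL4, of the lysyl oxidase family, was 10.1-fold lower. The chemokine genes CCL8 and CCL3L3 were 7.55-fold and 6.75-fold lower, and CCL8 was above background on 1 of the 3 Activin A + BMP4 arrays.

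**Figure D1:**
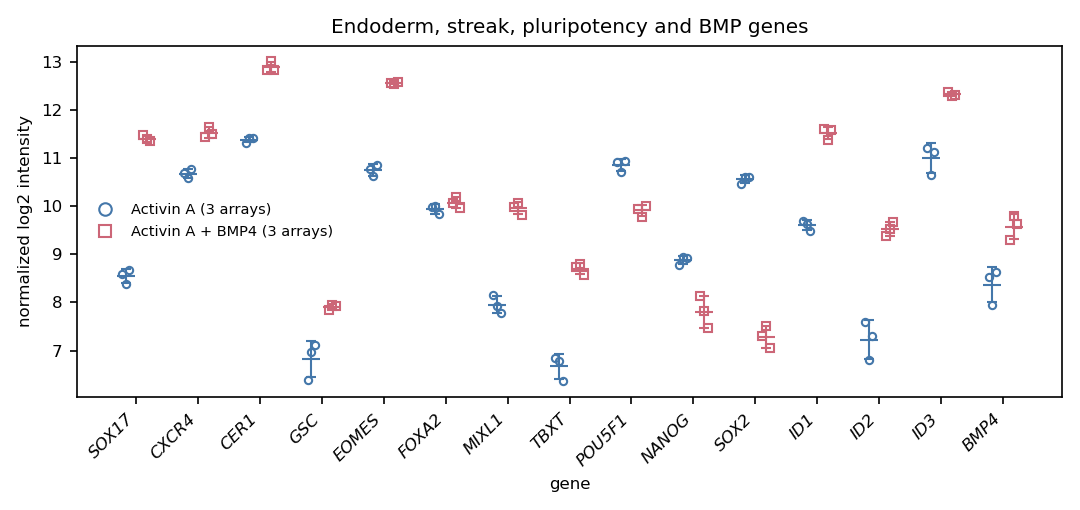
Normalized log2 intensity (vertical axis) of the 15 fixed genes (horizontal axis) on the 3 arrays of each treatment, with the mean and SD as bars. SOX17 lies higher with BMP4 by 2.85 and SOX2 lower by 3.27 on the log2 scale, while the arrays of FOXA2 overlap between treatments.

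Of 19 tested genes of the definitive endoderm list, 14 were higher, 2 lower and 3 not past the threshold, with the same counts when adjusted over the list alone. The median log2 difference was 0.96 (camera adjusted p = 5.74e-06; adjusted p = 0.0921 with an estimated correlation). Besides SOX17, EOMES, a T-box factor of mesendoderm, was 3.52-fold higher, and GATA4, not above background with Activin A, was at least 2.57-fold higher (1.79-fold under normexp). CXCR4, a chemokine receptor used as a surface marker of endoderm, was 1.81-fold higher by its brighter probe (limma adjusted p = 4.82e-04), while its other probe differed by 0.51 (limma adjusted p = 0.0959). FOXA2, a forkhead factor of endoderm, differed by 0.13 ± 0.11 SE (limma adjusted p = 0.386). The members that fell were SHISA2, by 1.00, and STC1, by 0.74 on the log2 scale.

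Of 10 tested primitive streak and mesendoderm genes, 9 were higher and 1 lower, the same counts as when adjusted over the list alone. Their median was 1.18 (camera adjusted p = 8.50e-06; adjusted p = 0.0921 with an estimated correlation). TBXT, the brachyury gene, was 4.09-fold higher, MIXL1 4.01-fold and FGF8 3.83-fold, and the member that fell was NODAL, by 0.60 on the log2 scale. The list shares 10 of its 20 genes with other lists. Among 13 tested Activin and Nodal target genes, 8 were higher and 1, NODAL, lower, or 10 and 1 adjusted over the list alone. The median was 0.92 (camera adjusted p = 1.98e-04; adjusted p = 0.0921 with an estimated correlation, and 0.114 without the genes it shares with other lists). CER1, a secreted Nodal antagonist, was 2.84-fold higher and GSC, the goosecoid gene, 2.11-fold higher. LEFTY1 and LEFTY2 did not pass the threshold, with log2 differences of 0.03 and -0.05 (limma adjusted p = 0.843 and 0.720).

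Among 12 tested BMP target genes, 7 were higher and 1 lower, or 8 and 1 adjusted over the list alone. Their median was 1.11, or 0.90 with the 3 genes not above background in a treatment at their bound (camera adjusted p = 0.00279; adjusted p = 0.0921 with an estimated correlation). SMAD6, an inhibitor of BMP signalling, was 7.07-fold higher, and ID2, ID1 and ID3, inhibitors of DNA binding, differed by log2 values of 2.29, 1.91 and 1.32, all higher. BMP4 itself was 2.30-fold higher. The member that fell was HEY1, not above background with BMP4 and at least 1.79-fold lower (1.40-fold under normexp).

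Pluripotency genes were lower on balance: of 20 tested, 10 were lower, 2 higher and 8 not past the threshold, with 10 and 3 adjusted over the list alone. On these arrays, where the feeder markers' median was -1.33, the pluripotency median was -0.48 (camera adjusted p = 0.00385, or 0.0921 with an estimated correlation). Fewer feeders alone would raise transcripts made only by the stem cell derived cells, so they would not account for falls of such genes. Which members the feeders also express was not tested. TERF1, a telomere-binding protein gene, was 3.67-fold lower and FGF2 2.84-fold lower. NANOG was 2.11-fold lower and POU5F1, which encodes OCT4, 1.93-fold lower. The members that rose were SALL4, by 0.62, and LIN28A, by 0.53 on the log2 scale.

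**Figure D2:**
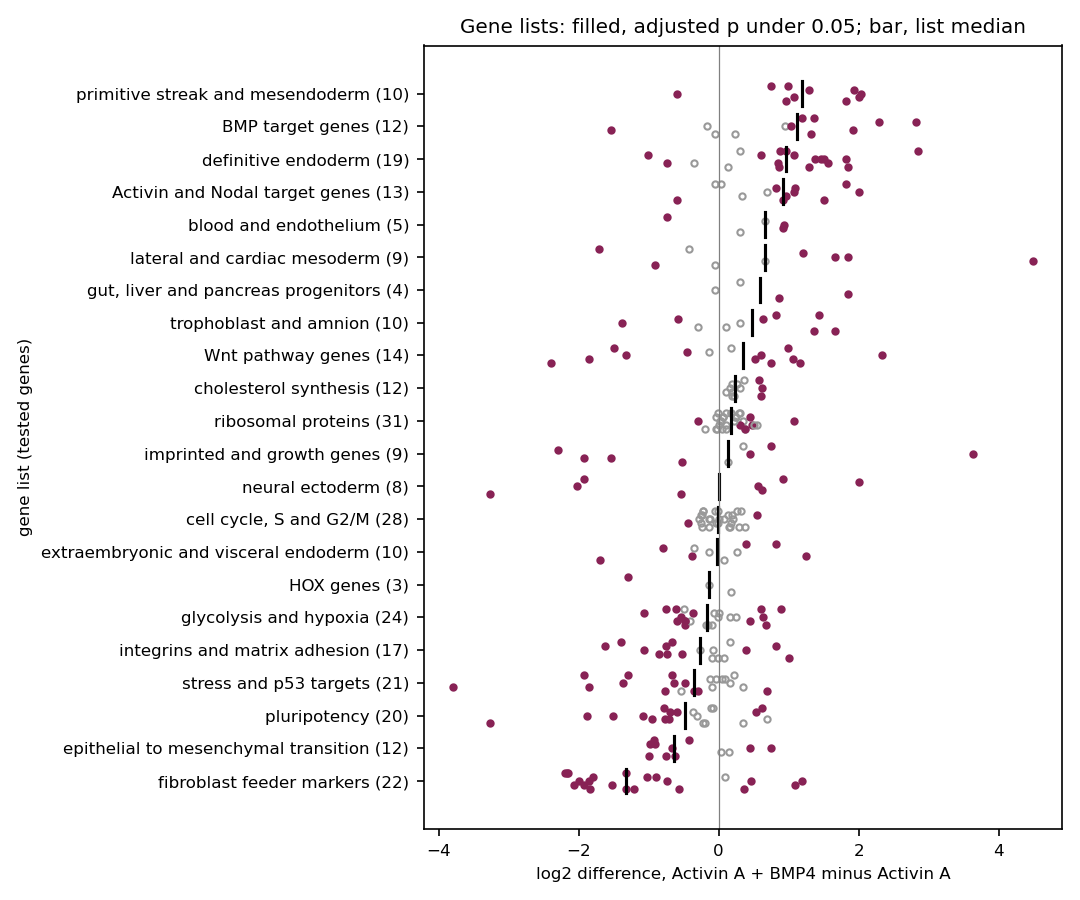
Log2 difference, Activin A + BMP4 minus Activin A (horizontal axis), of each tested member of the 22 gene lists (vertical axis, number tested in brackets), with filled points past the adjusted threshold and a bar at the list median. Medians run from 1.18 for primitive streak and mesendoderm to -1.33 for fibroblast feeder markers, and genes not above background in a treatment are drawn at their fitted difference.

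The fibroblast feeder markers, fixed because the cells had been grown on fibroblasts, moved with the treatments. Of 22 tested, 17 were lower, 4 higher and 1 not past the threshold, with 17 and 4 adjusted over the list alone. Their median was -1.33 (camera adjusted p = 5.74e-06; adjusted p = 0.101 with an estimated correlation). LOX, which encodes lysyl oxidase, was 4.58-fold lower, the surface glycoprotein gene THY1 4.48-fold and the homeobox gene PRRX1 4.46-fold lower. The members that rose were COL5A2, by 1.19, CCL2, by 1.08, FBLN1, by 0.46, and COL5A1, by 0.37 on the log2 scale.

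**Figure D3:**
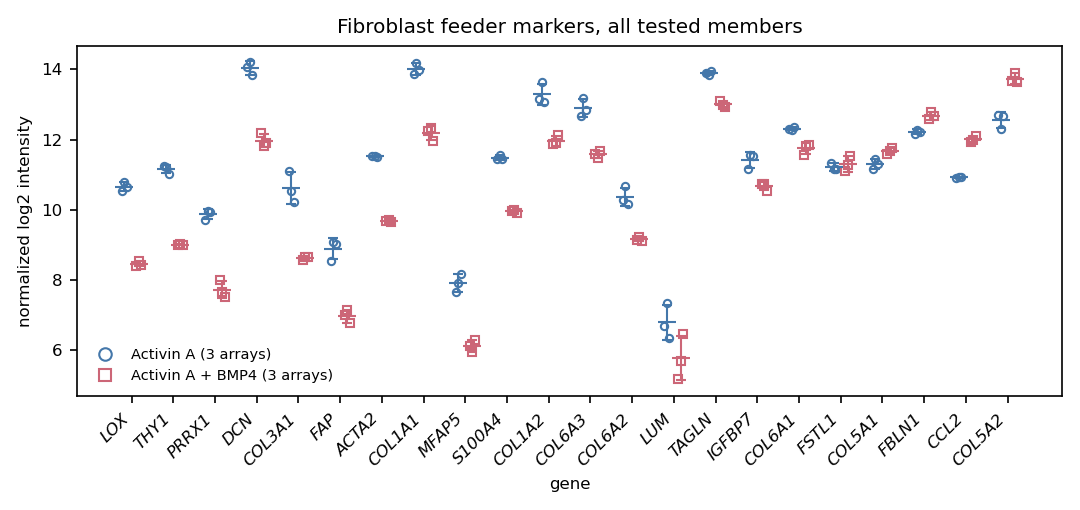
Normalized log2 intensity (vertical axis) of the 22 tested fibroblast feeder markers (horizontal axis, ordered by difference) on the 3 arrays of each treatment, with the mean and SD as bars. LOX lies lowest relative to Activin A and COL5A2 highest.

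Lists of matrix and adhesion genes missed the threshold, on arrays where the feeder markers' median differed by -1.33. In the epithelial to mesenchymal transition list, 8 of 12 tested genes were lower and 2 higher, with a median of -0.64 (camera adjusted p = 0.0583, and 9.18e-04 to 0.216 over the alternatives). TGFBI was 2.00-fold, CDH11 1.97-fold and VIM, the vimentin gene, 1.90-fold lower. The members that rose were CDH2, by 0.75, and CLDN6, by 0.45 on the log2 scale, and CDH1 was 1.34-fold lower. The list holds both epithelial and mesenchymal genes, so its median does not give the direction of a transition. Of 17 tested integrin and matrix adhesion genes, 8 were lower and 3 higher (median -0.26, camera adjusted p = 0.0867, and 0.0198 to 0.348 over the alternatives). ITGA2 was 3.07-fold, CD44 2.62-fold and LAMC1 2.09-fold lower.

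Lists of other lineages missed the threshold as well, on arrays where the feeder markers' median differed by -1.33. Whether the members that fell did so through fewer feeders was not tested. Of 9 tested genes of lateral and cardiac mesoderm, 4 were higher and 2 lower (median 0.67, camera adjusted p = 0.275), or 5 and 3 adjusted over the list alone. The members that rose were APLNR, GATA4, HAND1 and BMP4. Those that fell were PDGFRB, 3.26-fold lower, and SNAI2, 1.87-fold lower. Of 5 tested blood and endothelial genes, 2 were higher and 1 lower (camera adjusted p = 0.162), or 3 and 1 adjusted over the list alone. SOX18 was 1.90-fold and TEK 1.89-fold higher, and ESAM, above background on 1 of 3 arrays with BMP4, 1.66-fold lower, a call lost without Activin A replicate 1 or 2 (limma adjusted p = 0.0532 and 0.0549). In the trophoblast and amnion list, 5 of 10 tested genes were higher and 2 lower (median 0.47, camera adjusted p = 0.156). HAND1 was 3.17-fold and KRT19 2.69-fold higher, and IGFBP3 was 2.60-fold lower. Of 10 tested extraembryonic and visceral endoderm genes, 3 were higher and 3 lower (camera adjusted p = 0.952). APOC1 was 2.38-fold and LAMA1 1.77-fold higher, and TTR, the transthyretin gene, above background on 2 of 3 arrays with BMP4, was 3.25-fold lower. Of 4 tested gut, liver and pancreas progenitor genes, 2 were higher and 0 lower (median 0.58, camera adjusted p = 0.0583), with FOXA3 1.82-fold higher. The members that rose, FOXA3 and GATA4, are also definitive endoderm members, and every tested member belongs to another list.

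Among 8 tested neural ectoderm genes, 4 were higher and 4 lower (camera adjusted p = 0.853). NCAM1, a neural cell adhesion molecule gene, was higher by a log2 difference of 2.00, and SOX3 was not above background with BMP4 and at least 2.66-fold lower (1.84-fold under normexp). Of 14 tested Wnt pathway genes, 7 were higher and 5 lower (camera adjusted p = 0.468). FRZB, a secreted Wnt antagonist gene, was 5.02-fold higher, DKK4, another antagonist gene, 5.29-fold lower and WNT5A 3.61-fold lower. The feeder markers' median differed by -1.33 on these arrays too, and a part of feeders in such falls was not tested. For the other lists of other lineages and of matrix and adhesion genes, counts adjusted over the list alone were the same. Signs differed in 3 of these lists. The extraembryonic endoderm median (-0.03) and mean (-0.06) were below 0 with a camera direction of higher, the neural median (0.01) was above 0 with the mean (-0.46) and camera below, and the Wnt mean (-0.00478) was below 0 with the median (0.35) and camera above.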

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

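All alternatives were listed before the data were examined, except the bounds under normexp, added afterwards. Named genes kept their direction in all 1352 comparisons of a gene with an alternative, and 42 of these, in ESAM, CCNB1, MCM4, DHCR7, P4HA1, RPL7A, RPS15 and RPLP1, no longer passed the threshold. The median log2 difference over all tested probes stayed between -0.0219 and 0.0110. Of 124 comparisons of counts or shares, 118 stayed close. Close means within 1.5 times the reported count, or inside the confidence interval of the reported share of higher genes. Genes higher at least 2-fold fell to 191 under normexp and 210 with detection on all 6 arrays, and genes lower at least 2-fold to 248 and 279. The stricter filter tests fewer genes; normexp changed the method and the offset together, and the cause was not tested. Under normexp the log2 differences of some dim genes were smaller by over 1.5 times with their calls kept: GATA4 1.07, IGSF21 -1.81, LCE2A -1.76, SOX3 -1.18, HOXC6 -0.71, H19 -1.51, ESAM -0.38, CCNB1 0.35 and RPL7A 0.72. Every named gene's bound was lower under normexp, from 11.5-fold for GRP to 1.08-fold for HOXC6, against 21.9-fold and 1.15-fold. With no background correction TXNIP (-8.38), IGSF21 (-5.18), LCE2A (-4.82) and HOXC6 (-4.49) differed by more, sizes that depend on the signal floor of 1. HOXC6 also differed more with the authors' values (-2.31). The share of higher genes was 46.0% with median scaling and 46.1% with the authors' values; the cause was not tested. Leaving out 1 array gave 1123 to 1274 genes higher and 1216 to 1343 lower, 319 to 353 and 430 to 453 of them at least 2-fold, 1384 to 1577 probes higher and 1475 to 1636 lower, and a share of 47.8% to 49.8%. Signal over background limits dim genes, which have only bounds.

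The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at 0.03, -0.03 and -0.05, and 2 of 6 arrays correlated best with their own number. With the replicate block, 1369 genes were higher and 1358 lower, the epithelial to mesenchymal list passed (camera adjusted p = 0.0497), and of the named genes MCM4 and RPS15 did not (limma adjusted p = 0.0666 and 0.0528). No other call of a list or named gene changed. With the chip as a random block (consensus correlation 0.0149), 1407 and 1458 genes were called, all of them called before.

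The following are camera adjusted p-values unless fry is named. With an estimated correlation, the BMP, Activin and Nodal, definitive endoderm, primitive streak, pluripotency and stress lists gave 0.0921, feeder markers 0.101 and cholesterol synthesis 0.130, and none passed. Without shared genes the Activin and Nodal list gave 0.114. Over the camera alternatives the lowest values of these lists were 2.73e-04 (BMP), 1.32e-05 (Activin and Nodal), 5.91e-09 (endoderm and feeder markers), 4.70e-07 (streak), 6.51e-05 (pluripotency), 2.75e-04 (stress) and 0.00391 (cholesterol). The epithelial to mesenchymal list passed with cyclic loess (0.0494), median scaling (0.0343), the authors' values (0.0389), no filter (9.18e-04) and detection on all arrays (0.0424). The integrin list passed with median scaling (0.0428), the authors' values (0.0389) and no filter (0.0198). The gut list passed with cyclic loess (0.0494), median scaling (0.0395) and the authors' values (0.0389), ribosomal proteins with cyclic loess (0.0164) and no filter (0.0161), and blood with detection on all arrays (0.0424). By fry, which does not compare a list with other genes, these also passed: lateral mesoderm and trophoblast (0.00212), blood and neural (0.010), epithelial to mesenchymal (0.00185), integrins (0.00910), gut (3.94e-05), HOX (0.0199), glycolysis (0.0140) and ribosomal proteins (0.0241). Directions turned only in lists that passed in neither setting: lateral mesoderm with detection on all arrays (0.628); extraembryonic endoderm with median scaling (0.975), the authors' values (0.984), no filter (0.842) and no shared genes (0.841); neural with no filter (0.719), detection on all arrays (0.745) and no shared genes (0.770); Wnt and imprinted without shared genes (0.814); and cell cycle with the mean of probes (0.930). Directions also turned without Activin A replicate 3 or Activin A + BMP4 replicate 3 for extraembryonic endoderm, and without Activin A replicate 1 or 3 or Activin A + BMP4 replicate 2 for cell cycle. Leaving out 1 array gave 0.755 to 0.955 for extraembryonic endoderm, 0.769 to 0.935 for cell cycle, 0.0411 to 0.0889 for epithelial to mesenchymal, 0.0446 to 0.181 for integrins, 0.0282 to 0.0788 for gut and 0.0374 to 0.111 for ribosomal proteins. The last 4 of these lists passed without Activin A replicate 3 or Activin A + BMP4 replicate 2 or 3 (epithelial to mesenchymal), Activin A + BMP4 replicate 3 (integrins), Activin A replicate 2 or Activin A + BMP4 replicate 1 (gut) and Activin A replicate 1 (ribosomal proteins). The causes were not tested.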

Other observations

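Genes outside the lineage lists moved as well. Of 21 tested stress and p53 target genes, 11 were lower with BMP4 and 1 higher, or 12 and 1 adjusted over the list alone (median -0.36, camera adjusted p = 0.00279; adjusted p = 0.0921 with an estimated correlation). The feeder markers' median differed by -1.33 on the same arrays. Besides TXNIP, EGR1, an immediate early gene, was 3.81-fold lower and CDKN1A, the gene of the cell cycle inhibitor p21, 3.60-fold lower. Of 12 tested cholesterol synthesis genes, 3 were higher and 0 lower, the same adjusted over the list alone (median 0.24, camera adjusted p = 0.0197; adjusted p = 0.130 with an estimated correlation). EBP was 1.54-fold, DHCR7 1.52-fold and SC5D 1.48-fold higher, and DHCR7 missed the threshold with the authors' values (limma adjusted p = 0.0541). In the glycolysis and hypoxia list, 9 of 24 tested genes were lower and 5 higher, or 10 and 5 adjusted over the list alone (median -0.17, camera adjusted p = 0.216). ADM, which encodes adrenomedullin, was 2.09-fold lower, HK1 1.69-fold lower and P4HA1 1.85-fold higher by its brighter probe, while its other probe differed by 0.09 (limma adjusted p = 0.798). The call of P4HA1 ended with the authors' values (log2 difference 0.08, limma adjusted p = 0.838) and with the mean of its probes (0.49, limma adjusted p = 0.0870).

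Of 28 tested cell cycle genes, CCNB1 was higher by 0.55, MCM4 was lower (fell by 0.44 on the log2 scale), and 26 did not pass the threshold (camera adjusted p = 0.952). Adjusted over the list alone, 0 were higher and 0 lower. Both calls were lost without some single arrays, with limma adjusted p up to 0.0989 for CCNB1 without Activin A + BMP4 replicate 3 and 0.122 for MCM4 without Activin A replicate 1. With the authors' values MCM4 differed by -0.23 (limma adjusted p = 0.329). These values are of its brighter probe, and its other probe differed by -0.21 (limma adjusted p = 0.274). Of 9 tested imprinted and growth genes, 3 were higher and 4 lower (camera adjusted p = 0.943), with DLK1 3.79-fold lower and H19 4.92-fold lower. H19 was above background on 1 of 3 arrays with BMP4, and its log2 difference of -2.30 was -1.51 under normexp. Of 31 tested ribosomal protein genes, 5 were higher and 1 lower (median 0.17, camera adjusted p = 0.0687), and 0 and 0 adjusted over the list alone. The largest differences past the threshold over all probes were those of RPL7A, by 1.08, RPS15 by 0.48 and RPLP1 by 0.45 on the log2 scale. RPL7A was above background on 2 of 3 Activin A arrays. The other probe of RPS15 differed by 0.16 and that of RPLP1 by 0.37, neither past the threshold (limma adjusted p = 0.274 and 0.0570). These 3 calls were also lost without some single arrays, with limma adjusted p up to 0.111, 0.0907 and 0.0860, and RPL7A differed by 0.62 without Activin A replicate 3. Of 3 tested HOX genes, HOXC6 was lower, at least 1.15-fold (1.08-fold under normexp), and not above background with BMP4 (camera adjusted p = 0.336). Whether fewer feeders played a part in the falls of this paragraph was not tested, and the feeder markers' median differed by -1.33. Signs differed for the imprinted list, whose median (0.14) was above 0 with the mean (-0.11) and camera below, and for the cell cycle list, whose mean (0.00851) was above 0 with the median (-0.00946) and camera below.

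The tests of a common factor, of chips, of 1 dilution factor and of cytokine against feeder genes were chosen after the results they bear on had been seen. In the first pattern, 14 of 19 endoderm genes and 9 of 10 streak genes were higher with BMP4, though neither list call held with an estimated correlation (camera adjusted p = 0.0921 for both). If fewer feeder cells had raised all transcripts of the stem cell derived cells by 1 factor, pluripotency genes would have risen alike. The endoderm list mean minus the pluripotency list mean instead rose by 1.55 (pooled SD 0.0764, n = 3 per treatment, exact permutation p = 0.1, the smallest possible). That of the streak list rose by 2.06. Both rises follow from the list results already seen. They argue against 1 common factor as the only cause, and a part played by fewer feeders is not excluded. The log2 difference between chips within Activin A + BMP4 was 0.468 of that between treatments (root mean squares 0.308 and 0.657), little above the differences on a single chip, 0.254 within Activin A + BMP4 and 0.277 within Activin A. But 1 of those chips held 1 array and no chip held both treatments, so chip and treatment cannot be told apart. An effect of BMP4 on the cells stays open beside it.

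In the second pattern, fibroblast feeder markers were lower with BMP4. A second list of 44 fibroblast genes that shares none with the first had a median difference of -0.90 over 38 tested genes (quartiles -1.38 and -0.52), with 31 lower and 3 higher. This is consistent with a smaller share of feeder fibroblasts, and embryonic cells that take on mesenchymal traits may express some of the same genes. A single dilution factor for every marker is argued against only if no other cells express the markers, because 17 were lower and 4 higher and the variance of their differences was 52.3 times their mean squared standard error. Dilution alone stays open where the stem cell derived cells also express some markers, which was not tested, as do fewer feeders with further regulation of single genes. No count of feeders was analysed here.

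In the third pattern, inflammatory cytokine genes were lower with BMP4: all 14 tested of a list of 26 fell, among them IL1B (5.05-fold lower) and CXCL8 (2.89-fold lower). The list was written after 5 of its genes had been seen among the falls. It leaves out the chemokine gene CCL2, which was 2.12-fold higher and is counted among the called feeder markers. Leukocytes in the Activin A cultures are argued against, since 0 of PTPRC, TYROBP, CD53, LAPTM5 and CORO1A were detected on any array. Of 7 tested genes in a list of 22 leukocyte genes 2 were lower, SRGN and CD14. Both, and AIF1, CD74 and CD68, which did not pass the threshold, were above background on all 3 Activin A arrays. SRGN was above background on 0 arrays with BMP4. Whether fewer feeder fibroblasts alone could account for the fall depends on how the genes are counted: the mean of the cytokine genes lay below that of all 21 called feeder markers (difference -0.83 ± 0.28 SE), but by -0.39 ± 0.20 against the 17 that fell, and by -0.48 ± 0.26 and -0.04 ± 0.18 without the 5 genes seen beforehand. For 3 cytokine genes not above background with BMP4 these are fitted values, and with them at their bound the differences were -0.67 ± 0.29, -0.22 ± 0.22, -0.34 ± 0.26 and 0.10 ± 0.18. Each SE comes from the spread over genes, treated as independent although measured on the same arrays, so it may be too small. Of these 8 comparisons 2 passed 2 SE, so this explanation cannot be told apart from regulation of the cytokine genes.

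Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave 3581 probes past the limma threshold and the highest other gave 0. With 10 splits no share under 0.05 can be reached. Every other split put arrays of both treatments in each group, so the difference between treatments added to the spread within groups. Few calls were therefore likely in them, and their count does not show what chance alone would give.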
